A study of Oryza sativa with 6 samples.

How the data were processed

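Messenger RNA was sequenced from rice grains of the mature period, from 3 libraries of the wild type line Zhenong 34 and 3 libraries of a mutant named sg34. Per the labels, libraries were made from total RNA with the SMARTER mRNA-Seq kit. The labels name no mutated gene, so no targeted gene could be examined as a test of the labels. They do not say that the replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. The series title also speaks of small RNA sequencing, which was not analysed here.

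The deposited table holds TPM, a length-corrected relative transcript abundance, with 2 decimals, although its name speaks of gene counts: the TPM of a library sum to between 967528 and 991476. Per the submitters' processing notes, HISAT2 2.1.0, StringTie, Bowtie2, RSEM and DESeq2 1.12.4 were used, with no role or order given. The same notes name the genome build mm10, a mouse build, which does not match the rice locus IDs in the table; the build is therefore taken as not given in the sources used here. TPM keep no sequencing depth, so the depth of each library is unknown and no counting intervals or detection limits are given. Mutant columns carry the names sg31, sg32 and sg33 where the labels write sg34. They were matched by replicate number to the mutant libraries, the only mutant in the series, and the mutant values rest on that reading. The authors' mean columns equalled the means of these columns, with 0 rows differing by over 0.0001. There were 0 further columns of per-sample values. No library pair was close to identical: correlations across genes of log2 values were at most 0.969.

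The design fixed before the data were examined was a count test, with limma on log2 values as the fallback for a table without counts. The fallback was used, since a count model needs counts. Rows with at least 1 TPM in at least 3 libraries were tested, which left 16917 of 55986 rows. TPM were divided by unweighted trimmed mean of M values (TMM) factors, trimming 30% of M and 5% of A values, and tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using moderated variances with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values in the text are from this limma test unless named otherwise. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The filter, the pseudocount, the trend and the unweighted factors were set after the unit and the values had been looked at and before any test was run.

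The scaling first run left the library sum out of the factors. A test on simulated data showed that this misplaced libraries of unequal sum, and the factors were corrected after the first results had been seen. The earlier scaling gave 318 higher and 307 lower genes, against 320 and 316 with the corrected factors. With the corrected factors, changes were simulated in 200 of 16917 genes for mutant against wild type. They were recovered in 11.2% of cases at 2-fold, 81.2% at 4-fold, 94.8% at 8-fold and 98.4% at 16-fold, averaged over 5 simulations. Of all calls, 5.43% were false. The changed genes were drawn only from more highly expressed genes, and noise was drawn independently for each gene. These rates therefore do not cover low genes or deviations that many genes of a library share.

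Before the data were examined, 16 gene lists with 219 members were fixed: starch synthesis, sucrose cleavage and transport, seed storage proteins, grain filling regulators, starch breakdown, endoplasmic reticulum chaperones, seed desiccation and abscisic acid, gibberellin, green tissue, grain size and brassinosteroid, phenylpropanoids, small RNA machinery, defence, heat shock, embryo and oil bodies, and antioxidant enzymes. Of the members, 2 were dropped because the deposited description contradicted the name. List members whose locus ID has no row in the table are not analysed here. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Terms of 10 to 500 tested genes from the deposited annotation were tested with 2-sided Fisher's exact tests against all tested genes with a term. Chromosome and order were read from the locus IDs, since no coordinates of this annotation were used. Neighbouring tested genes called in the same direction were counted against 10000 shuffles in a one-sided permutation test.

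Genes were called detected in 1 line only at 5 TPM or more in all 3 libraries of one line and 0.1 TPM or less in all 3 of the other. The planned rule was in counts, and these TPM limits were set after the values had been looked at. Named genes follow a rule fixed in advance: the 8 highest and 8 lowest fold changes among described genes past the threshold, at least 2-fold, with a mean of at least 10 TPM (planned as CPM) in the higher group and no overlap between groups; the 3 members with the smallest p of a called list and the 1 such member of any other list; the 2 highest expressed starch and storage protein genes; and up to 3 genes detected in 1 line only per direction. Of the genes this rule names, 2 are not reported here. Alternatives were another scaling, filter, pseudocount or variance model, the replicate number as a block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.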

Results

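Grain transcripts of the rice mutant sg34 were compared with those of its wild type, Zhenong 34, in 3 libraries each, to ask which transcripts differed between the lines at grain maturity. The table gave TPM for 55986 rows, of which 22090 were listed at 0 in all 6 libraries, and the depth of the libraries is unknown. Wild type replicate 1 stood apart from the other libraries. The seed storage protein list took 5.82% of its nominal TPM total, against 32.3% and 24.6% in wild type replicates 2 and 3 and 38.3%, 35.8% and 29.5% in the mutant libraries. The first principal component held 54.6% of the variance and placed that library at -93.7, the other wild type libraries at -12.0 and -23.1, and the mutant libraries between 16.7 and 63.2. Across genes, correlations of log2 values ran from 0.874 to 0.952 within the wild type, from 0.943 to 0.969 within the mutant and from 0.774 to 0.913 between the lines; genes are not independent replicates.

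A peroxisomal acyl-CoA oxidase gene and a glutathione S-transferase gene rose in the mutant, and genes for a GABA transaminase and a gibberellin 2-oxidase fell. Several prolamin storage protein genes were also called higher, but other prolamin copies had lower means in the mutant, and some of these calls depended on single libraries. The acyl-CoA oxidase 4 gene LOC_Os06g23870, whose product acts in fatty acid breakdown, went from 0.030 ± 0.052 TPM in the wild type to 100.3 ± 12.4 TPM in the mutant (SD, n = 3), a log2 difference of 6.89 ± 0.16 (SE) with limma adjusted p = 1.05e-05. The GABA transaminase 1 gene LOC_Os10g15240, which encodes a GABA-degrading enzyme, went from 109.0 ± 31.8 to 0.043 ± 0.038 TPM (SD, n = 3), a log2 difference of -6.41 ± 0.18 (SE) with limma adjusted p = 1.20e-05. In total 320 genes were higher and 316 lower in the mutant by limma, and 302 and 292 of these differed at least 2-fold.

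The gibberellin 2-beta-dioxygenase 2 gene LOC_Os05g11810, of a family that inactivates gibberellins, fell by 5.96 on the log2 scale, from 86.9 ± 26.8 to 0.11 ± 0.07 TPM (SD, n = 3). The FAM63A gene LOC_Os06g50630 fell by 4.998 on the same scale. The RPP13-like disease resistance gene LOC_Os01g57310 fell by 4.32, the xylem cysteine proteinase 1 gene LOC_Os11g23770 by 4.02 and the MYB3 gene LOC_Os02g09670 by 3.75 on the log2 scale, with limma adjusted p between 7.74e-05 and 0.00121. The F-box/kelch gene LOC_Os11g08830 was listed at 0 in all 3 mutant libraries and at 23.5 to 36.5 TPM in the wild type. Among genes that rose, the glutathione S-transferase gene LOC_Os10g38630, of a detoxifying family, had 55.4 ± 9.18 TPM in the mutant (SD, n = 3) and at most 0.05 TPM in the wild type. The glycolate oxidase gene LOC_Os08g09860 and the gene LOC_Os08g27630, described as an IscA-like iron-sulfur assembly protein, were listed at 0 in all wild type libraries and at 24.5 to 33.4 and 10.7 to 15.6 TPM in the mutant. The nearest protein match given for LOC_Os08g27630 is a gag-pol precursor, so its description is uncertain. Other gene names here and above are likewise deposited descriptions and were not checked against the sequences. The nearest matches given for LOC_Os10g15240 and LOC_Os05g11810 are less specific, a putative aminotransferase and an unknown protein of an oxygenase superfamily. For LOC_Os11g23770 the only domain given is a cathepsin propeptide inhibitor domain.

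**Figure D1:**
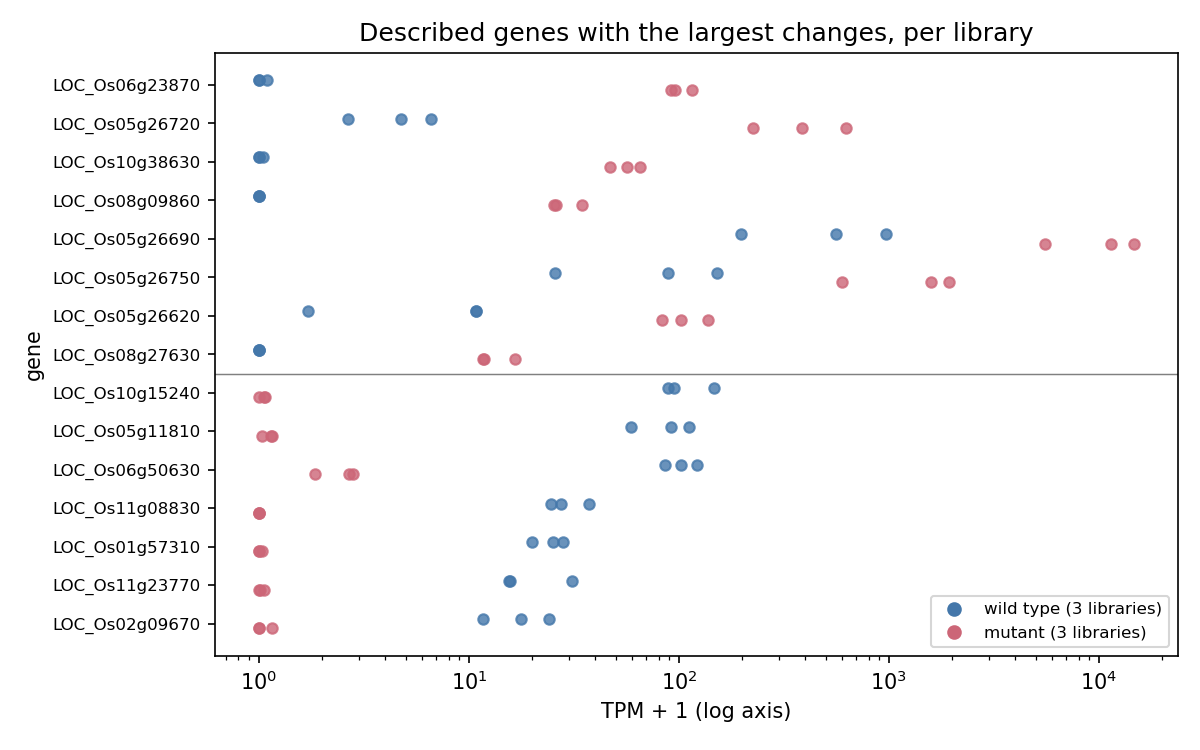
TPM + 1 on a log axis for the described genes with the 8 highest log2 differences and 7 of the 8 lowest, with 1 point for each of the 3 wild type and 3 mutant libraries. The groups do not overlap for any of these genes; LOC_Os06g23870 lies at up to 0.09 TPM in the wild type and from 91.2 TPM in the mutant.

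The prolamin genes LOC_Os05g26720, LOC_Os05g26690, LOC_Os05g26750 and LOC_Os05g26620 on chromosome 5, which encode alcohol-soluble storage proteins, rose by 6.86, 4.88, 4.64 and 4.54 on the log2 scale with limma adjusted p of 0.00131, 0.0342, 0.0480 and 0.0321. LOC_Os05g26690 reached 10510 ± 4630 TPM in the mutant against 575.2 ± 387.9 TPM in the wild type (SD, n = 3). Other copies on chromosome 5 had lower means in the mutant, LOC_Os05g26480 with a log2 difference of -4.10 (adjusted p = 0.209) and LOC_Os05g26359 with -1.98 (adjusted p = 0.581). LOC_Os05g26359 had 131.7, 9001 and 7667 TPM in wild type replicates 1, 2 and 3 and 282 to 423 TPM in the mutant. Of 24 tested prolamin rows 7 were called higher and 0 lower. Their largest difference was a fall, -8.77 for LOC_Os12g16880 on chromosome 12 (limma adjusted p = 0.0501). Summed over the 14 tested prolamin rows on chromosome 5, prolamins took 2.35% and 2.43% of TPM in wild type replicates 2 and 3, 0.0908% in replicate 1, and 2.60%, 3.29% and 1.40% in the mutant libraries. The chromosome 5 copies carry the same description and may share reads, which was not measured, so each value is uncertain. The calls of LOC_Os05g26690, LOC_Os05g26750 and LOC_Os05g26620 were each lost in 4 of 6 fits without a library: without wild type replicate 3, mutant replicate 1 or mutant replicate 2 for each, without wild type replicate 2 for the first and second, and without mutant replicate 3 for LOC_Os05g26620, with adjusted p from 0.0641 to 0.196. They were also lost with no filter on low values (adjusted p = 0.105, 0.102 and 0.0753) and with the replicate block (0.161, 0.168 and 0.0870), where log2 differences were 4.86, 4.62 and 4.52 and 4.88, 4.64 and 4.54. With a pseudocount of 0.1 the calls of LOC_Os05g26750 (0.0568) and LOC_Os05g26620 (0.0771) were lost, and with at least 5 TPM in 3 libraries that of LOC_Os05g26750 (0.0672).

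The limma counts moved with single libraries: 407 genes passed without wild type replicate 3, and 344, 320 and 421 passed without mutant replicates 1, 2 and 3. Against 50.3% of calls higher in the mutant with TMM scaling, 38.2% were higher when TPM were not rescaled, with 186 genes higher and 301 lower. The median log2 difference of all tested genes was -0.01 after scaling and -0.43 without it, and differences are given relative to the scaled values. Groups did not overlap for 23.6% of tested genes, where chance gives 10%.

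The granule-bound starch synthase gene (Wx, LOC_Os06g04200), which makes amylose, had 2741 ± 578 TPM in the wild type and 10430 ± 1933 TPM in the mutant (SD, n = 3). Its log2 difference of 2.46 ± 0.58 (SE) had limma adjusted p = 0.0821, and it was higher in 3 of 3 mutant libraries than in any wild type library. Its adjusted p ranged from 0.00355 with library weights to 0.444 with no filter over all alternatives, and was 0.0112 with no variance trend. Of the 24 tested starch synthesis genes, 0 passed over all genes and 0 adjusted over the list alone, and the list median was 0.05, or -0.47 without rescaling (camera adjusted p = 0.453). The branching enzyme gene BEIIa had a log2 difference of 1.26 ± 0.27 (SE, limma adjusted p = 0.0638, or 0.0190 without wild type replicate 2 and 0.00269 with library weights), and the amyloplast transporter gene BT1-1 one of -0.21 ± 0.39 (SE, limma adjusted p = 0.809), or -0.06 without wild type replicate 2.

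**Figure D2:**
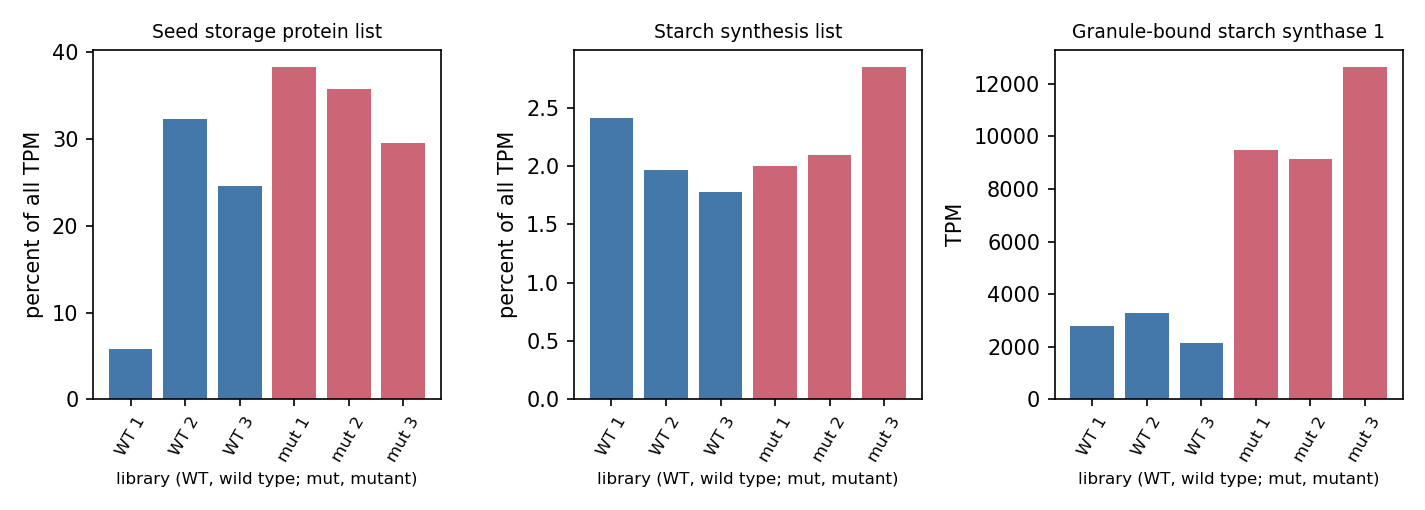
Bars give each library's percent of the nominal TPM total in the seed storage protein list (left) and the starch synthesis list (middle), and the TPM of granule-bound starch synthase 1 (right), for 3 wild type (WT) and 3 mutant (mut) libraries. Wild type replicate 1 has 5.82% of its nominal TPM total in storage proteins, and the starch synthase gene lies at 2140 to 3292 TPM in the wild type and 9145 to 12651 TPM in the mutant.

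Seed storage proteins were the 1 list of 16 that camera called, higher in the mutant with adjusted p = 0.0170 and a median log2 difference of 1.56 over 17 members. With an estimated correlation the adjusted p was 0.933. Of its members 0 passed over all genes and 0 adjusted over the list alone; the glutelin genes GluA1, GluB2, GluB4 and GluD1 had log2 differences of 2.06 ± 1.31, 1.096 ± 0.44, 2.63 ± 1.41 and 1.34 ± 0.72 (SE), and the prolamin gene Pro13-d 3.20 ± 1.93 (SE). Without wild type replicate 1 these differences were 0.87, 0.67, 0.98, 0.74 and 0.98. With library weights GluB2 (adjusted p = 0.0185) and GluD1 (0.0479) passed. The list moved with wild type replicate 1: without that library its adjusted p was 0.272, and without mutant replicate 1 it was 0.0830. With no filter on low values it was 0.1445. The table describes GluD1 as a glutelin type-B 2 gene, and glutelin copies may share reads, which was not measured, so single values are uncertain.

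The heat shock list held 1 gene that rose and 1 that fell among 8 tested, over all genes and adjusted over the list alone. The transcription factor gene HSFA2c (LOC_Os10g28340), an activator of heat shock genes, rose by 1.39 ± 0.18 (SE) on the log2 scale with limma adjusted p = 0.00822, or 0.277 without rescaling, 0.0717 with the replicate block and 0.0628 without mutant replicate 2. The small heat shock protein gene HSP16.9B (LOC_Os01g04380) fell by 3.05 ± 0.52 (SE) with limma adjusted p = 0.0257; it was named after its values were seen and has a near copy beside it, so its value is uncertain. The list's camera adjusted p was 0.500. The mixed fry test, which tests against no change in either direction and makes no comparison with other genes, gave adjusted p under 0.05 for heat shock (1.87e-05), small RNA machinery (0.000478), starch synthesis (0.0132) and grain size (0.0166). Of the last 3 lists, 0 members passed by limma over all genes and 0 adjusted over the list alone, and 17.25% of all tested genes had an unadjusted limma p under 0.05.

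In the other lists 0 members passed over all genes by limma as described, and camera called 0 of them. Some members passed in alternatives: with library weights NAC20 (adjusted p = 0.00239), CIN2 (0.00192), CAB-b (0.00521), CYP78A13 (0.00850), PR1a (0.0131) and APX2 (0.00516), and with no variance trend NAC20 (0.0479). Grain filling regulators had 9 tested members and a camera adjusted p of 0.248; adjusted over the list alone 2 were higher, the endosperm transcription factor genes NAC20 at 1.29 and NAC26 at 1.38. Sucrose cleavage and transport also had 9 tested members and a camera adjusted p of 0.248, with 1 higher adjusted over the list alone, the cell wall invertase gene CIN2 at 1.39. In the green tissue list 2 of 12 were higher and 1 lower adjusted over the list alone, namely CAB-b at 2.36, CHLG at 1.21 and PAO at -0.62, and its camera adjusted p was 0.453. NAC26, CHLG and PAO were named after their values were seen. Over all genes, CIN2 (adjusted p = 0.0652) and CAB-b (0.0669) had adjusted p of 0.0466 and 0.0496 without wild type replicate 1. Single members with the smallest p were ABA8ox2 at 0.84 (adjusted p = 0.283) for desiccation, 7S-globulin at 2.72 (0.438) for embryo, CHI at 1.24 (0.238) for phenylpropanoids, PR1a at 1.19 (0.332) for defence and APX2 at 0.80 (0.151) for antioxidant enzymes. Without wild type replicate 1, ABA8ox2 was at 0.49, 7S-globulin at 0.64, CHI at 0.74 and APX2 at 1.01 (adjusted p = 0.0411), and without mutant replicate 2 PR1a was at 0.76. For grain size the member with the smallest p was CYP78A13 at -1.26 (0.0823) and for small RNA machinery SGS3 at -0.61 (0.228); the grain size list had a median of 0.06 and a mean of -0.03, with camera pointing up. GID1 at 0.48 (0.370) for gibberellin and IRE1 at 0.27 (0.464) for endoplasmic reticulum chaperones had signs that turned without rescaling, and were at 0.28 and 0.15 without wild type replicate 1. Camera adjusted p was 0.453 for starch breakdown, embryo and small RNA machinery, 0.248 for desiccation (0.00626 without wild type replicate 3 and 0.0257 without rescaling), 0.895 for gibberellin, grain size and chaperones, 0.832 for phenylpropanoids, 0.632 for defence and 0.500 for antioxidant enzymes.

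In the mutant only, 36 genes on 9 chromosomes were detected, and 34 genes on 10 chromosomes in the wild type only. Besides LOC_Os06g23870, the most abundant in the mutant were LOC_Os10g35100 at 76.7 ± 20.6 TPM, which was listed at 0 in the wild type, and LOC_Os10g39470 at 56.2 ± 21.3 TPM (SD, n = 3). Besides LOC_Os10g15240, those in the wild type were LOC_Os10g18090 at 142.1 ± 51.1 TPM and LOC_Os07g01910 at 92.4 ± 41.5 TPM (SD, n = 3). The deposited description of these 4 genes is empty; the nearest protein match given for LOC_Os10g18090 is a putative antifreeze glycoprotein precursor.

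Of 741 annotation terms, 5 were enriched among higher genes by Fisher's exact test and 0 among lower genes, against 18 and 18 at an unadjusted p under 0.05. Of the 320 higher genes 184 carried a term, and of the 316 lower genes 150. The enriched terms were cysteine-type peptidase activity with 6 of 33 genes (adjusted p = 0.00365), protein desumoylation and SUMO-specific protease activity with 4 of 11 each, ADP binding with 6 of 50 and endopeptidase activity with 4 of 20. Terms can share genes, so they are not separate results. ADP binding also held 4 of 50 among lower genes (Fisher's exact adjusted p = 0.589). Without wild type replicate 1 the number of enriched terms was 1, and without wild type replicate 2 it was 0. Neighbouring tested genes changed in the same direction in 70 pairs, against a mean of 11.9 and a highest value of 27 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest they can give). The shuffles treat genes as independent, so copies of a gene side by side, such as the prolamins, may add pairs. The number of pairs was 39 without wild type replicate 3, 31 without mutant replicate 1, 31 without mutant replicate 2 and 43 without mutant replicate 3, each with permutation p = 1e-04. Chromosome 11 had 8.67% of its tested genes changed and chromosome 9 had 1.63%.

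**Figure D3:**
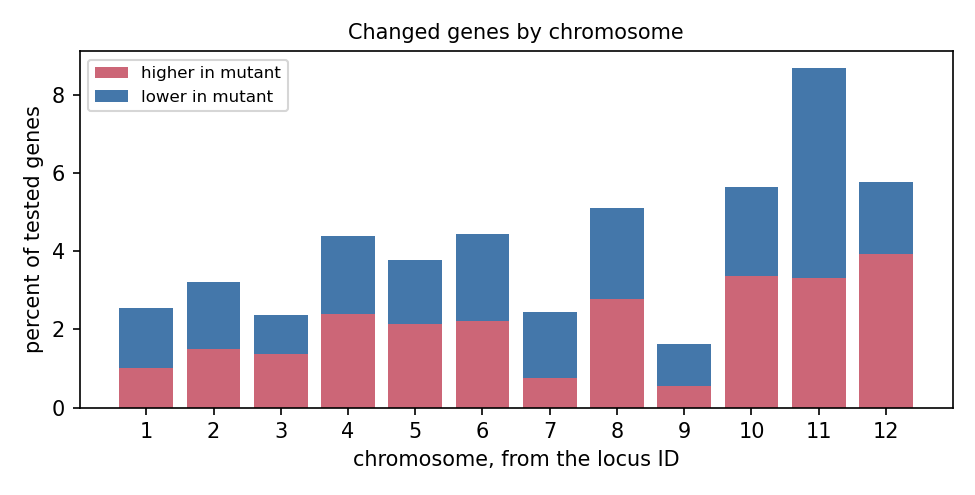
Stacked bars give the percent of tested genes on each chromosome that were higher (red) or lower (blue) in the mutant by limma. The total is 8.67% on chromosome 11 and 1.63% on chromosome 9.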

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

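The alternatives without rescaling, with other factors, filters at 5 TPM, pseudocounts, library weights and no variance trend, and the other limits for genes detected in 1 line only, were chosen after seeing the data. In each alternative, 0 of the 636 called genes that were tested there had the other direction. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.54, 0.003 and -0.37, and with the replicate block 131 genes were higher and 123 lower, all at least 2-fold. Without rescaling 186 were higher, all at least 2-fold. With at least 5 TPM in 3 libraries fewer genes were tested and 129 were higher and 140 lower, 126 and 136 at least 2-fold. With library weights 2137 were higher and 1779 lower, 1050 and 613 at least 2-fold, and the cause was not tested. With a pseudocount of 5, 302 were higher and 263 lower, 134 and 113 at least 2-fold. A larger pseudocount shrinks the log2 differences of low genes. Of the 636 called genes, 315 met the filter of at least 5 TPM in 3 libraries. Leaving out each library gave 165 to 364 higher and 155 to 370 lower genes, 165 to 356 and 155 to 343 at least 2-fold, 0 to 6 enriched terms, 37 to 40 genes in the mutant only and 34 to 45 in the wild type only. Lists called higher numbered 0 with no filter, an estimated correlation or fry, 2 without rescaling and 0 to 2 without a library; desiccation was the list gained without rescaling and without wild type replicate 3.

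At a limit of 2 TPM, 66 genes were in the mutant only and 73 in the wild type only, and at 20 TPM 6 and 9. With 0 required in the mutant, 21 were in the wild type only. Signs turned without rescaling for GID1 (-0.007), IRE1 (-0.15), gibberellin (adjusted p = 0.867) and grain size (0.867), and with library weights for grain size (0.745), heat shock (0.745) and phenylpropanoids (0.669). They turned in some fits without a library for defence (0.297 to 0.928), chaperones (0.397 to 0.971), gibberellin (0.539 to 0.971), grain size (0.723 to 0.971) and phenylpropanoids (0.341 to 0.928). DESeq2, limma-voom and the limits of 10 and 50 counts were not run, since the table holds no counts.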

Other observations

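All tests here were chosen after the results were seen, except those of neighbouring pairs and transposon descriptions among genes detected in 1 line only and of other splits. The tests were rerun after the scaling and the search for transposon descriptions had been corrected, and the conditions for excluding an explanation were made stricter after a first run.

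Of 24 tested rows described as prolamins, 7 were higher and 0 lower by limma. LOC_Os12g16880 had 53.2, 4249 and 3389 TPM in wild type replicates 1, 2 and 3 and at most 1.1 TPM in the mutant (log2 difference -8.77, adjusted p = 0.0501), and LOC_Os05g26480 had 115.2, 2847 and 3057 TPM there and at most 43.6 TPM in the mutant (adjusted p = 0.209). Disease resistance genes were changed in 8 of 47 rows (17.0%). Rows whose description or domain names Ulp1 or SUMO, not all of them necessarily proteases, were changed in 8 of 64 (12.5%). Outside these groups 3.72% and 3.73% of tested genes were changed. Ribosomal protein genes were changed in 1 of 348 rows (0.287%), against 3.83% outside that group. Fisher's exact tests gave adjusted p of 0.000163 for prolamins, 0.000875 for disease resistance, 0.00528 for Ulp1 and 0.000171 for ribosomal proteins, over 8 groups picked after the calls were seen; copies of a gene are not independent. The other 4 groups, glutathione S-transferases, histones, F-box proteins and seed allergens, had adjusted p from 0.366 to 1.

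The 70 genes detected in 1 line only were weighed first. Transposon-like gene models are a candidate source of part of them: 11.4% (8 of 70) carried such a description, 4.72 times the share of 2.42% among other tested genes, not matched for expression. Among all 636 changed genes the share was 8.49% (54 genes), so genes detected in 1 line only are not alone in the excess. Of the 70 genes, 21.4% had a deposited description, against 65.8% of other tested genes. Segments that differ between the genomes stay open. For these genes 0 directly adjacent pairs were found where shuffles gave a mean of 0.138, too few for the test to decide. The count misses genes that lie near without being adjacent, such as LOC_Os06g04195 and LOC_Os06g04399, both in the wild type only. Among all 636 changed genes there were 70 same-direction neighbouring pairs, against a shuffle mean of 11.9, to which copies of a gene side by side may add. Windows of the 50 nearest tested genes held up to 17 changed genes in either direction, against a mean of 1.87. Stage or composition cannot be told apart from line by design, although wild type replicate 1 lay nearer the other wild type libraries at 92.2% of 77 genes chosen without it.

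Wild type replicate 1 stood apart in storage protein transcripts. A library of the other line is argued against, since it lay nearer the wild type at 71 of those 77 genes. Dilution of endosperm RNA by other tissue is argued against as the only source, as far as the starch synthesis genes mark endosperm. Medians of starch synthesis and storage proteins, on unscaled TPM, differed by 3.34 on the log2 scale (95% bootstrap interval 2.1 to 4.64). Dilution would lower both alike. The interval resamples list members of this library alone, which are not independent, so it may be too narrow. The starch list took 2.416% of the nominal TPM total in wild type replicate 1, against 1.965% and 1.777% in wild type replicates 2 and 3. The green tissue list took 0.0347% in wild type replicate 1, against 0.0042% and 0.0078% in wild type replicates 2 and 3. Some admixture of other tissue is therefore not excluded. An earlier stage of grain filling may contribute and cannot be told apart. On scaled values the green tissue median of 0.577 had an interval of -0.10 to 1.74. The storage protein and embryo medians of wild type replicate 1 were -3.28 and -2.71 relative to the other wild type libraries. These are on scaled values too. On unscaled TPM the storage protein, embryo and green tissue medians were -2.80, -2.01 and 1.2, for which no interval was computed.

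The granule-bound starch synthase gene had a log2 difference of 2.46 that did not pass by limma (adjusted p = 0.0821), and it was not tested against the differences of other starch genes. A rise of starch synthesis genes together is argued against by the median of the other 23 members, 0.04 (95% bootstrap interval -0.12 to 0.23), and wild type replicate 1 alone by the difference of 2.26 without it. A chromosome segment that differs between the lines may underlie the difference and stays open: 3 of the 50 nearest tested genes were changed, as many as in 28.6% of windows. These were LOC_Os06g04195, LOC_Os06g04350 and LOC_Os06g04399, all lower in the mutant. LOC_Os06g04195 lies directly beside the starch synthase gene among tested genes, and LOC_Os06g04399 lies 15 tested genes away. Their wild type means were 7.03 and 10.3 TPM, and both were listed at 0 in the mutant and detected in the wild type only. The window count does not weigh such nearness or complete loss. An effect of the mutation itself was not tested.

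For the 636 changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one, and the highest other split gave 0. With 10 splits no share under 0.05 can be reached.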
